A study of Homo sapiens with 6 samples.

How the data were processed

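Poly(A) RNA of MOLM-13 cells was sequenced as paired-end reads of 75 bp, per the labels' protocols. Cells were grown in medium with 10% serum, transduced, kept for up to 15 days and sorted for GFP. The deposited table holds raw counts for 30017 gene symbols in 6 libraries, not normalized. Per the submitters' processing notes, FastQC 0.11.7, HISAT2 2.0.5 and featureCounts 1.5.2 were used, and the notes name the genome builds GRCh37 and GRCh38 without saying which the counts rest on. The annotation and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes, and genes with near-identical copies, are uncertain. Groups and replicate numbers were taken from the sample titles.

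Counts were analysed in R 4.3.3. Genes at 0 in all libraries numbered 10379. Genes were kept by filterByExpr of edgeR 4.0.16, which left 13435, and scaled by TMM factors. UBE2N shRNA was compared with control shRNA by edgeR's quasi-likelihood test (two-sided) on all 6 libraries with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are UBE2N shRNA minus control shRNA, with standard errors from the quasi-likelihood F statistic. Levels are CPM, counts scaled to a common library size with the TMM factors, given as mean ± SD of 3 libraries. The biological coefficient of variation was 6.86%. Total counts between 15209519 and 24956842 set the counting precision of each level.

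Before the data were examined, 23 gene lists, the design, the rule for the genes named and the alternatives were fixed. Of 821 listed symbols, 9 were matched by an older symbol and 1 was not in the table. The 22 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. By fry, 11 lists passed in a common direction and 18 in either direction; fry does not compare a list with other genes. The genes named are UBE2N and 15 fixed genes, the 8 largest rises and 8 largest falls among calls with at least 5 CPM in the higher group and no overlap between groups, and in each list up to 3 called members per direction with at least 1 CPM, or the 2 with the highest CPM where none was called. Not every gene this rule selects is printed. Genes named outside this rule are identified as chosen after their values were seen.

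On simulated counts for this comparison with 200 changed genes, the edgeR test recovered 78% of genes changed 1.5-fold and 92.9% of those changed 2-fold among 13332 genes, and 3.41% of its calls were wrong. Camera called 20 of 20 shifted and 0 of 180 unshifted lists over 13435 genes. These genes were simulated independently, while the estimated correlation within the real lists reached 0.312 (sterol biosynthesis). The simulation therefore does not show how camera with the preset correlation behaves on lists whose members vary together. Alternatives were other size factors (RLE, upper quartile, total counts), no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, and leaving out each library. A fit that removes each library's smooth trends on GC content and transcript length, from GENCODE transcripts matched by symbol for 93.7% of tested genes, was added after seeing the data. It also removes each library's mean deviation, and its median log2 fold change over genes was -0.0286, against 0.0025 in the main fit. In simulated data with a GC trend added to 1 library, this fit recovered 81.5% of genes changed 1.5-fold among 12507 genes, with 6.32% of calls wrong, against 50% recovered and 1.43% of calls wrong without it. Pairs of libraries of a group differed by 2.53 to 23.8 times counting noise (chi-square per degree of freedom), so no library was a copy of another.

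For 7-base sites, 3′ UTRs of the longest coding transcript were searched in 9743 genes with at least 5 CPM, and log2 fold changes were adjusted for length and base composition. To compare site locations without the effect of picking sites, the genes were divided at random into 2 parts. These steps and the permutation tests were run in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.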

Results

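Gene expression was measured by RNA-seq in MOLM-13 cells, a human acute myeloid leukaemia line of monocytic type with a KMT2A fusion and an activated FLT3 receptor. The cells carried either a scrambled control shRNA or an shRNA against UBE2N, delivered by lentivirus, and were selected by their GFP signal. Each group held 3 libraries. Total counts were 23233150, 21043706 and 24956842 in control replicates 1 to 3, and 23510454, 15209519 and 19891365 in UBE2N shRNA replicates 1 to 3. The first principal component carried 39.7% of the variance and separated the groups. The second component carried 23.1% and placed UBE2N shRNA replicate 1 at -22.8, against 2.06 for replicate 2 and 13.1 for replicate 3. Ribosomal protein genes took 10.2% of the counts in UBE2N shRNA replicate 1, 12.2% and 12.7% in the other UBE2N shRNA libraries, and 11.3% to 11.4% in the controls.

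The comparison asked which transcripts differ when UBE2N, the ubiquitin-conjugating enzyme that assembles non-degradative ubiquitin chains in innate immune signalling and DNA damage tolerance, is lowered in these leukaemia cells. UBE2N fell from 146 ± 7.05 CPM (SD, n = 3) in control cells to 106 ± 5.79 CPM (SD, n = 3) in UBE2N shRNA cells. Its log2 fold change was -0.46 with a standard error of 0.06 (edgeR quasi-likelihood adjusted p = 0.00148), which left 72.7% of the control level (95% interval 66.8% to 79.2%). The interval uses a normal approximation, which makes it somewhat too narrow with 3 libraries per group. All UBE2N shRNA libraries, at 110, 108 and 99.4 CPM, lay below all control libraries, at 150.0, 138 and 149.5 CPM. UBE2N lies on chromosome 12 from 93405684 to 93441947 in GRCh38. The count table names genes by symbol only. A total of 21 called genes fell further than UBE2N did.

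The largest rise among genes that reached 5 CPM was that of CHAC1, a glutathione-degrading enzyme induced by ATF4, which went from 1.81 ± 0.33 to 11.6 ± 0.55 CPM (log2 fold change 2.67, SE 0.14, edgeR adjusted p = 2.14e-06; n = 3 per group here and in all values that follow). It was followed by XIRP1, an actin-binding protein of muscle (2.25), ADM2, a peptide hormone of the adrenomedullin family (2.17), ANGPTL4, a lipoprotein lipase inhibitor (2.10), and RGS1, a regulator of G-protein signalling (1.83; 8.12 ± 0.57 to 28.8 ± 1.41 CPM). The growth factor response genes EGR3 (1.63), EGR1 (1.57) and DUSP1 (1.52) completed the 8 largest rises. The largest fall among genes that reached 5 CPM was that of ALDH1A3, a retinoic acid synthesising enzyme, from 54.6 ± 2.51 to 27.7 ± 2.31 CPM (log2 fold change -0.99, SE 0.08, edgeR adjusted p = 2.45e-05). B3GNT7 (-0.68), MPEG1, a pore-forming protein of macrophages (-0.68), SOX13 (-0.67), PPP1R14C (-0.66), DTX4 (-0.62) and HLA-DRA (-0.60) were also among the largest falls. Among these genes, 3 calls were lost when single libraries were left out, with an edgeR adjusted p of up to 0.125: B3GNT7 without control replicate 2 or 3 or UBE2N shRNA replicate 2, PPP1R14C without control replicate 1 or 3 or UBE2N shRNA replicate 2, and HLA-DRA without any 1 control or UBE2N shRNA replicate 2. The 3′ UTR of B3GNT7 holds the 8-base sequence GAAGAGCA, taken up in the closing observations.

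In all, 507 of 13435 tested genes passed an adjusted p of 0.05, of which 424 rose and 83 fell. Of the 88 that changed at least 2-fold, 87 rose and 1 fell, against 153 and 17 without UBE2N shRNA replicate 1. Without UBE2N shRNA replicate 1, 3030 of 13521 tested genes passed (1610 higher and 1420 lower), a share to set beside the list counts given below for that fit. Passing genes numbered 214, 243, 218, 247 and 503 without control replicates 1, 2 and 3 and UBE2N shRNA replicates 2 and 3 in turn. With trends on GC content and transcript length removed from each library, a step chosen after seeing the data, 1299 genes passed, 620 higher and 679 lower.

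**Figure D1:**
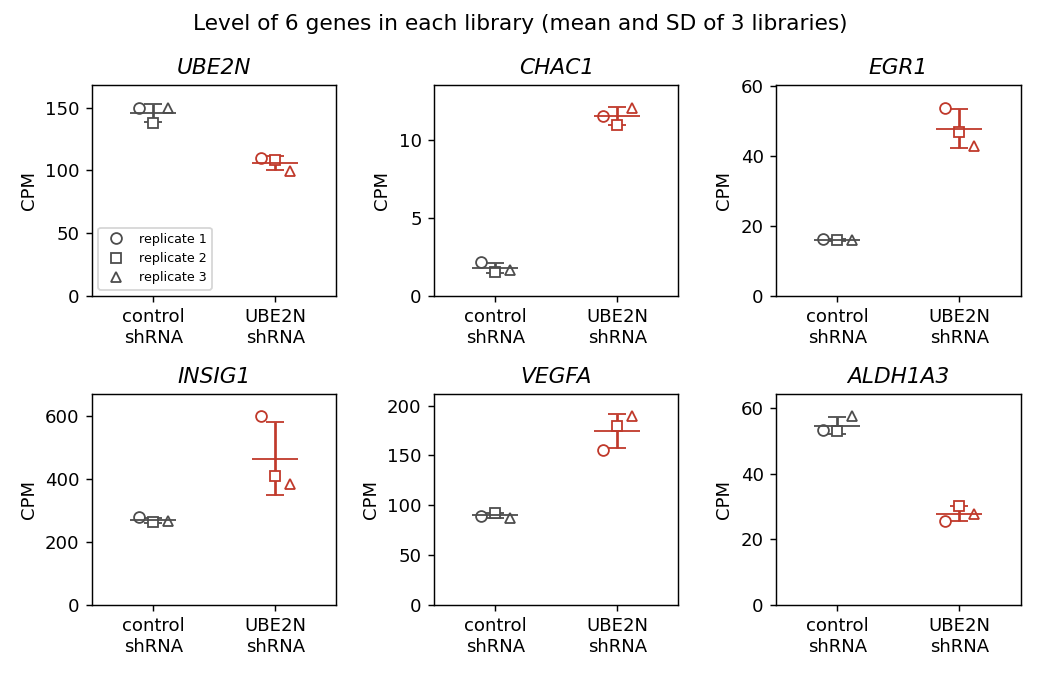
CPM of UBE2N, CHAC1, EGR1, INSIG1, VEGFA and ALDH1A3 in each control shRNA library (grey) and UBE2N shRNA library (red), with symbols for the replicate number and a bar for the mean and SD of 3 libraries. UBE2N averaged 146 CPM in control and 106 CPM in UBE2N shRNA libraries, and in each panel the groups do not overlap.

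MAPK feedback and immediate early genes, which respond within minutes to growth factor signalling, rose together: 16 of 30 tested members rose, none fell, and 14 did not pass (19 rose when adjusted over the list alone). EGR2 went from 1.13 ± 0.07 to 3.89 ± 0.11 CPM (log2 fold change 1.77, edgeR adjusted p = 0.000158), and EGR1 from 16.1 ± 0.27 to 47.9 ± 5.56 CPM (edgeR adjusted p = 3.48e-06). FOS, which had the smallest p of all genes, went from 66.3 ± 2.22 to 185 ± 1.27 CPM (log2 fold change 1.48, edgeR adjusted p = 1.67e-07) and is named here after its values were seen. The 3′ UTR of EGR3, another riser of this list, also holds GAAGAGCA. The list's median log2 fold change was 0.48 (camera adjusted p = 9.73e-17; adjusted p = 0.0611 with an estimated correlation). The median was 0.65 in UBE2N shRNA replicate 1, which stood apart on the second component, and 0.38 and 0.39 in replicates 2 and 3. With single libraries left out, 11 (without control replicate 1 or 3) to 18 members (without UBE2N shRNA replicate 1) rose.

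Genes of the integrated stress and unfolded protein response rose in 20 of 42 tested members, with no member falling (25 rose and 1 fell when adjusted over the list alone). Besides CHAC1, the largest rises were those of SLC6A9, a glycine transporter, from 0.27 ± 0.10 to 1.36 ± 0.08 CPM (log2 fold change 2.29, edgeR adjusted p = 0.00165), and STC2, a secreted glycoprotein, from 4.30 ± 0.80 to 11.1 ± 0.97 CPM (log2 fold change 1.36, edgeR adjusted p = 0.000245). The median was 0.28 (camera adjusted p = 3.98e-12; adjusted p = 0.116 with an estimated correlation), at 0.32 in UBE2N shRNA replicate 1 and 0.23 and 0.26 in replicates 2 and 3. With UBE2N shRNA replicate 1 left out, 25 members were higher and 6 lower, and 14 to 20 rose without other single libraries.

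Sterol biosynthesis genes rose in 13 of 27 tested members and fell in none (20 rose when adjusted over the list alone). HMGCS1, which makes the precursor of mevalonate, went from 152 ± 5.92 to 273 ± 66.3 CPM (log2 fold change 0.85, edgeR adjusted p = 0.00328). INSIG1, a sterol-sensing regulator, went from 269 ± 8.16 to 466 ± 117 CPM (0.79, edgeR adjusted p = 0.00601), and MVD, a mevalonate pathway enzyme, from 75.1 ± 1.30 to 125 ± 6.37 CPM (0.73, edgeR adjusted p = 3.04e-05). The median was 0.39 (camera adjusted p = 8.35e-12; adjusted p = 0.184 with an estimated correlation), at 0.63 in UBE2N shRNA replicate 1 and 0.24 and 0.27 in replicates 2 and 3. Without any 1 of the controls 8 members rose, and 17 did without UBE2N shRNA replicate 1.

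Glycolysis and hypoxia genes rose in 14 of 32 tested members and fell in none (19 rose when adjusted over the list alone). ADM, a vasodilator peptide, went from 1.17 ± 0.21 to 3.03 ± 0.37 CPM (log2 fold change 1.37, edgeR adjusted p = 0.00279). ENO2, a glycolytic enolase, rose by 0.97 on the log2 scale, and VEGFA, the angiogenic growth factor, went from 89.6 ± 2.54 to 175 ± 17.4 CPM (0.96, edgeR adjusted p = 2.32e-05). The median was 0.30 (camera adjusted p = 6.05e-13; adjusted p = 0.123 with an estimated correlation), at 0.37 in UBE2N shRNA replicate 1 and 0.21 and 0.22 in replicates 2 and 3. Without any 1 of the controls 9 members rose, and 18 rose and 1 fell without UBE2N shRNA replicate 1.

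**Figure D2:**
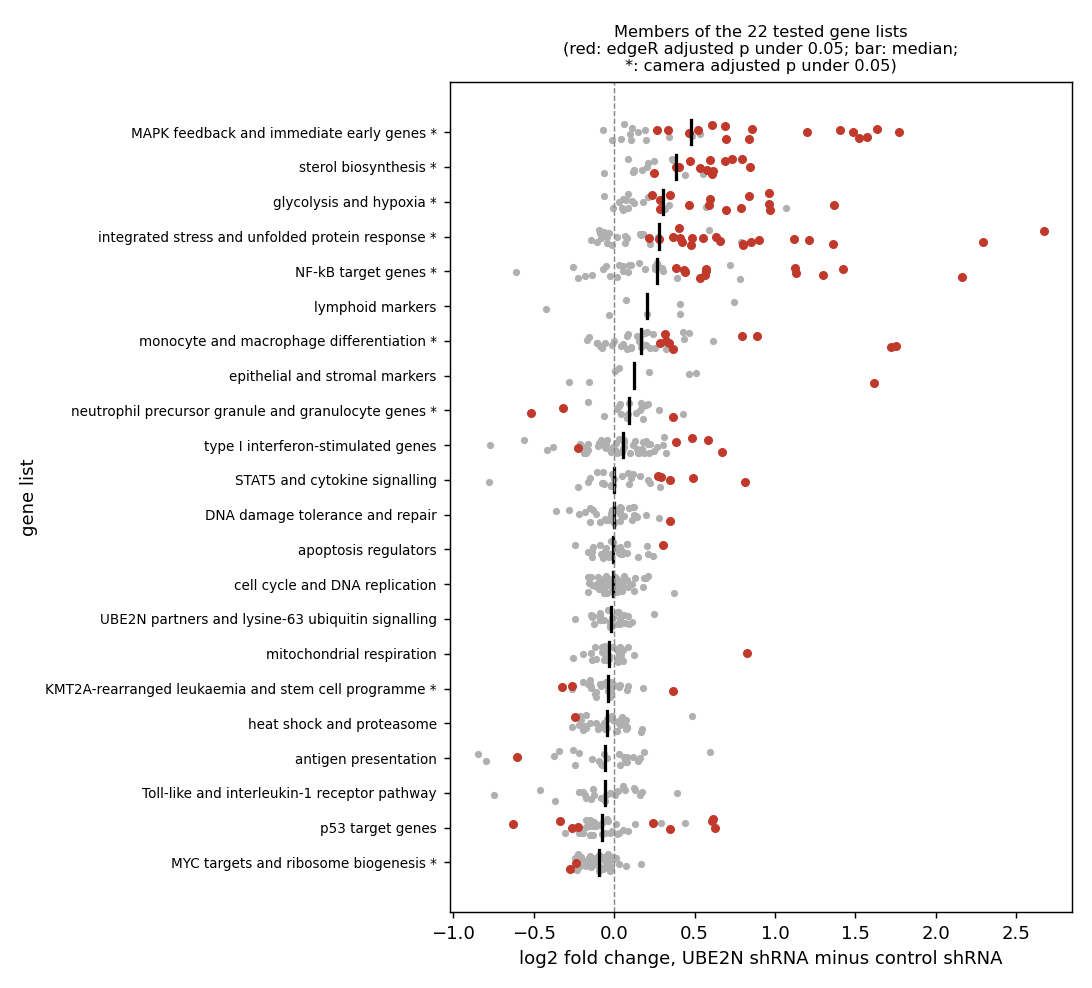
Log2 fold change (UBE2N shRNA minus control shRNA) of each tested member of the 22 tested gene lists, ordered by the list's median (black bar). Red points are members with an edgeR adjusted p under 0.05, and an asterisk marks the 9 lists with a camera adjusted p under 0.05, from a median of 0.48 for MAPK feedback and immediate early genes to -0.09 for MYC targets and ribosome biogenesis.

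NF-kB target genes rose in 12 of 39 tested members and fell in none (18 rose and 2 fell when adjusted over the list alone). The chemokine CCL4 went from 0.23 ± 0.09 to 1.01 ± 0.41 CPM (log2 fold change 2.16, edgeR adjusted p = 0.0154), a low level whose call was lost without control replicate 1 or 3, with an edgeR adjusted p of up to 0.103. CCL3, which has the near-identical copy CCL3L3, went from 3.62 ± 0.50 to 9.70 ± 1.03 CPM (1.42, edgeR adjusted p = 0.000177), and TRAF1, a signalling adaptor, from 3.48 ± 0.72 to 8.50 ± 0.64 CPM (1.30, edgeR adjusted p = 0.000521). NFKBIA, the inhibitor that NF-kB induces, did not pass, at 23.6 ± 1.43 and 24.1 ± 1.26 CPM (log2 fold change 0.03, SE 0.08). The median was 0.27 (camera adjusted p = 2.98e-08; adjusted p = 0.0611 with an estimated correlation), and 8 members rose without control replicate 1 or 3. Leaving out UBE2N shRNA replicate 1 gave 18 members higher and 3 lower.

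The signalling components upstream did not pass the test. None of the 28 tested UBE2N partners and ubiquitin signalling genes was called (0 also when adjusted over the list alone; camera adjusted p = 0.350). Its cofactor UBE2V2 stood at 156 ± 18.8 and 159 ± 22.6 CPM (log2 fold change 0.03, SE 0.11), the kinase IKBKB, whose 3′ UTR holds GAAGAGCA, at 174 ± 5.66 and 179 ± 11.7 CPM (0.04, SE 0.06), and the ubiquitin ligase TRAF6 at 23.4 ± 1.75 and 22.3 ± 2.13 CPM (-0.06, SE 0.09). UBE2V1 stood at 2.29 ± 0.60 and 2.36 ± 0.57 CPM (0.02, SE 0.24), and it is overlapped by a read-through gene. None of the 24 tested Toll-like and interleukin-1 receptor pathway genes was called (0 also when adjusted over the list alone; median -0.05, camera adjusted p = 0.0671). The adaptor MYD88 had a log2 fold change of -0.14 (SE 0.06), and the kinases IRAK4, IRAK1 and IRAK3 had 0.07 (SE 0.06), -0.12 (SE 0.06) and 0.0092 (SE 0.06). Without UBE2N shRNA replicate 1, 2 partner genes were higher and 6 lower, and 1 receptor pathway gene was higher and 3 lower, in a fit where 3030 of all 13521 tested genes passed. With the GC and length trends removed, 0 receptor pathway genes were higher and 5 lower. The receptor subunit CD14 was below the count filter, with 2 to 4 counts in each library.

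Monocyte and macrophage differentiation genes rose in 9 of 43 tested members and fell in none (16 rose when adjusted over the list alone). ITGAX, the integrin CD11c, went from 95.4 ± 10.1 to 177 ± 25.2 CPM (log2 fold change 0.89, edgeR adjusted p = 0.000521). TREM1, a myeloid receptor, rose by 0.80 and CSF1R, the receptor for macrophage colony-stimulating factor, by 0.33, from 80.3 ± 4.58 to 101 ± 4.26 CPM (edgeR adjusted p = 0.0134). ITGAM, the integrin CD11b, did not pass at 113 ± 7.4 and 127 ± 2.16 CPM (0.17, SE 0.06), but did without UBE2N shRNA replicate 1 (edgeR adjusted p = 0.0255) and with the GC and length trends removed (edgeR adjusted p = 0.0414), and reached an edgeR adjusted p of 0.547 without control replicate 1. The median was 0.17 (camera adjusted p = 7.01e-07; adjusted p = 0.184 with an estimated correlation). Without control replicate 1 or UBE2N shRNA replicate 2, 1 member rose, and without UBE2N shRNA replicate 1, 19 were higher and 1 lower. Without UBE2N shRNA replicate 2 or control replicate 1 the calls for TREM1 and CSF1R were lost, as they were without control replicate 2, and CSF1R also without control replicate 3 (edgeR adjusted p of up to 0.115).

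In the list of neutrophil precursor granule and granulocyte genes, 1 of 21 tested members rose and 2 fell (8 rose and 2 fell when adjusted over the list alone). MPO, myeloperoxidase, went from 89.8 ± 2.56 to 116 ± 8.28 CPM (log2 fold change 0.37, edgeR adjusted p = 0.00784), while the granule protease CTSG went from 474 ± 3.27 to 381 ± 33.0 CPM (-0.32, edgeR adjusted p = 0.0195) and IGLL1, a surrogate light chain, fell by 0.52. The list's test was upward (median 0.09, camera adjusted p = 0.0207; adjusted p = 0.211 with an estimated correlation) and did not pass without control replicate 1 or UBE2N shRNA replicate 3 (camera adjusted p of up to 0.0820), nor with the replicate number as a block or the GC and length trends removed. Leaving out UBE2N shRNA replicate 1 gave 12 members higher and 2 lower. The call for MPO was lost without control replicate 2 or 3, and those for CTSG and IGLL1 without any 1 control or UBE2N shRNA replicate 2 (edgeR adjusted p of up to 0.182).

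The KMT2A-rearranged leukaemia and stem cell programme had 1 riser and 2 fallers among 34 tested genes (1 and 2 also when adjusted over the list alone). DOT1L, the histone methyltransferase recruited by KMT2A fusions, went from 187 ± 5.92 to 241 ± 3.52 CPM (log2 fold change 0.36, edgeR adjusted p = 0.00201), whereas ADCY9, an adenylyl cyclase, fell by 0.32 and the homeobox gene HOXA10 fell by 0.26. HOXA9 stood at 23.2 ± 0.58 and 22.5 ± 1.99 CPM (-0.03, SE 0.08), MEIS1, whose 3′ UTR holds GAAGAGCA, at 48.9 ± 0.79 and 43.9 ± 2.66 CPM (-0.16, SE 0.07), FLT3 at 535 ± 11.3 and 516 ± 42.3 CPM (-0.05, SE 0.06) and MYC at 715 ± 4.59 and 706 ± 36.1 CPM (-0.02, SE 0.05), none of them called. The list as a whole lay lower (median -0.04, camera adjusted p = 0.0391; adjusted p = 0.486 with an estimated correlation), but not without control replicate 1 or 2 or UBE2N shRNA replicate 2 or 3 (camera adjusted p of up to 0.242), with no filter on low counts, with the GC and length trends removed, or by fry (fry adjusted p = 0.290). Its median was 0.02 in UBE2N shRNA replicate 1, against -0.07 and -0.13 in replicates 2 and 3. In the fit without UBE2N shRNA replicate 1, 2 members were higher and 11 lower. The calls for ADCY9 and HOXA10 were lost without all single libraries but UBE2N shRNA replicate 1 (edgeR adjusted p of up to 0.196).

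MYC targets and ribosome biogenesis genes lay lower as a list, with 46 of 50 tested members below 0 and 4 above. The nucleolar proteins NOLC1 (317 ± 9.21 to 263 ± 13.8 CPM, log2 fold change -0.27, edgeR adjusted p = 0.0219) and NAT10 (192 ± 2.76 to 163 ± 9.10 CPM, -0.23, edgeR adjusted p = 0.0444) fell and no member rose (8 fell when adjusted over the list alone). The median was -0.09 (camera adjusted p = 4.97e-07; adjusted p = 0.0611 with an estimated correlation). Both gene calls were lost without all single libraries but UBE2N shRNA replicate 1, without which 19 members were lower and 2 higher, and 21 were lower with the GC and length trends removed. Without the other single libraries in turn their edgeR adjusted p reached 0.218.

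**Figure D3:**
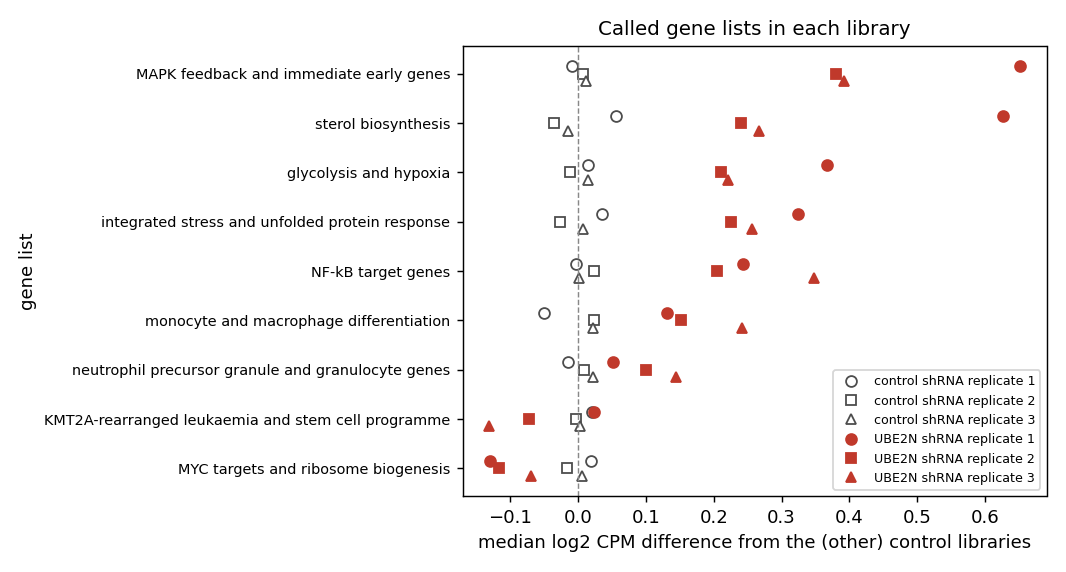
Median log2 CPM difference of the members of the 9 called lists in each library, from the mean of the controls (UBE2N shRNA libraries, filled red) or of the other controls (control libraries, open grey). MAPK feedback and immediate early genes reached 0.65 in UBE2N shRNA replicate 1, and 0.38 and 0.39 in replicates 2 and 3.

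The remaining lists did not pass. Type I interferon-stimulated genes had 4 risers and 1 faller among 52 (camera adjusted p = 0.272; 4 and 1 also when adjusted over the list alone): the antiviral genes IFIT2 (log2 fold change 0.67), IFIT3 (0.58) and SAMD9L (0.38) and the apoptosis factor XAF1 (54.3 ± 1.31 to 75.8 ± 1.44 CPM, 0.48) rose, and TRIM22 fell by 0.23. In antigen presentation, HLA-DRA, a class II chain, fell from 9.37 ± 0.23 to 6.19 ± 1.03 CPM and the other 25 genes did not pass (camera adjusted p = 0.209; 1 rose and 4 fell when adjusted over the list alone). Of 39 p53 target genes, 5 rose and 4 fell (camera adjusted p = 0.0826; 6 and 8 when adjusted over the list alone). Among them SESN2 (0.63), whose 3′ UTR holds GAAGAGCA, PMAIP1 (0.62) and BTG2 (0.61) rose, EDA2R (-0.63), CYFIP2 (-0.33) and POLH (-0.26) fell, and CDKN1A, the cell cycle inhibitor, stood at 592 ± 7.31 and 586 ± 23.5 CPM (-0.01, SE 0.05). Of 29 STAT5 and cytokine signalling genes, 5 rose (camera adjusted p = 0.255; 5 rose and 1 fell when adjusted over the list alone), led by SOCS3 (0.81), IL10RA (0.49) and PIM1 (0.35). SAMD9L is named after its values were seen.

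In these 4 lists, calls lost without single libraries had an edgeR adjusted p of up to 0.246. Those for IFIT3, TRIM22, EDA2R, CYFIP2 and POLH were lost without any 1 control or UBE2N shRNA replicate 2, and CYFIP2 also without UBE2N shRNA replicate 3. PMAIP1 was lost without control replicate 1 or 2 or UBE2N shRNA replicate 2, PIM1 without control replicate 1 or 3, and IL10RA without control replicate 1. Without UBE2N shRNA replicate 1, 7 interferon-stimulated genes were higher and 6 lower, 4 antigen presentation genes higher and 4 lower, 6 p53 targets higher and 10 lower, and 8 STAT5 and cytokine signalling genes higher and 4 lower. With the GC and length trends removed, 6 p53 targets rose and 12 fell, 1 antigen presentation gene rose and 5 fell, and 6 STAT5 and cytokine signalling genes rose and 2 fell. TRIM22 was also lost with the replicate number as a block (edgeR adjusted p = 0.0575) and EDA2R with DESeq2 (DESeq2 adjusted p = 0.0666).

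None of 55 cell cycle and DNA replication genes was called (0 also when adjusted over the list alone; camera adjusted p = 0.602). The helicase subunits MCM4 and MCM7 had log2 fold changes of -0.06 (SE 0.07) and 0.0022 (SE 0.05), and without UBE2N shRNA replicate 1, 11 members were lower and 4 higher. Single members were called in 5 further lists. POLI, a translesion polymerase, rose by 0.34 among 36 DNA damage tolerance and repair genes (camera adjusted p = 0.760; 1 rose also when adjusted over the list alone), whose median and mean were above 0 while the test pointed down. HSP90AB1, a chaperone, fell by 0.24 among 37 heat shock and proteasome genes (camera adjusted p = 0.0827; 3 rose and 7 fell when adjusted over the list alone). COX7C, a cytochrome oxidase subunit whose 3′ UTR holds GAAGAGCA, went from 146 ± 4.07 to 260 ± 31.9 CPM (0.83, edgeR adjusted p = 0.000177) among 33 mitochondrial respiration genes (camera adjusted p = 0.267; 1 rose and 1 fell when adjusted over the list alone). BMF, a BH3-only protein, rose by 0.30 among 29 apoptosis regulators (camera adjusted p = 1.00; 1 rose also when adjusted over the list alone), whose median was below 0 and mean above. VWF rose from 1.21 ± 0.27 to 3.62 ± 0.70 CPM (1.61, edgeR adjusted p = 0.00151) among 8 epithelial and stromal markers (camera adjusted p = 0.360; 1 rose also when adjusted over the list alone). The calls for POLI, HSP90AB1 and BMF were lost without any 1 control or UBE2N shRNA replicate 2 (edgeR adjusted p of up to 0.243), HSP90AB1 also without UBE2N shRNA replicate 3, with robust dispersion and with the replicate number as a block, and POLI with the GC and length trends removed. Without UBE2N shRNA replicate 1, 6 heat shock and proteasome genes were higher and 9 lower, 5 respiration genes higher and 7 lower, 2 repair genes higher and 5 lower, and 5 apoptosis regulators higher and 1 lower. With the GC and length trends removed the counts were 1 and 8 for heat shock and proteasome genes, 1 and 2 for respiration genes, 1 and 4 for repair genes, 3 and 2 for apoptosis regulators, and 1 and 3 for cell cycle and DNA replication genes.

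Some lists that were not called passed under single alternatives. By fry, which does not compare a list with other genes, the Toll-like and interleukin-1 receptor pathway (fry adjusted p = 0.0226) and p53 targets (fry adjusted p = 0.0310) moved down and interferon-stimulated genes up (fry adjusted p = 0.0226). Without control replicate 3, the median log2 fold change of the list Toll-like and interleukin-1 receptor pathway was -0.05 (camera adjusted p = 0.0289). The median log2 fold change of the list antigen presentation was -0.08 without UBE2N shRNA replicate 3 (camera adjusted p = 0.0436). In turn, the median log2 fold change of the list cell cycle and DNA replication was -0.07 without UBE2N shRNA replicate 1 (camera adjusted p = 0.0336). Without control replicate 2, the median log2 fold change of the list heat shock and proteasome was -0.04 (camera adjusted p = 0.0448).

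None of 7 lymphoid markers was called (0 also when adjusted over the list alone; camera adjusted p = 0.272), with CD3D at 2.12 ± 0.22 and 2.45 ± 0.16 CPM and CD79A at 0.71 ± 0.19 and 0.76 ± 0.10 CPM. Of the erythroid and megakaryocytic markers, 3 could be tested, too few for a list test, and none was called. EPOR stood at 15.9 ± 1.02 and 17.8 ± 0.46 CPM and TFR2 at 11.3 ± 1.41 and 10.5 ± 0.93 CPM. None of the 9 called lists passed with an estimated correlation. For NF-kB target genes that correlation was 0.00323, below the preset 0.01, yet the camera adjusted p went from 2.98e-08 to 0.0611. Higher correlation among members therefore does not account for the loss of that call. In the other called lists the estimated correlation was 0.0155 to 0.312, and how much of their loss it explains was not tested. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, and a single hairpin per group cannot separate loss of UBE2N from other effects of the hairpins.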

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

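The GC and length correction was chosen after seeing the data, and the other alternatives before. UBE2N fell under all 16 alternatives. Counts of calls stayed within 1.5 times 507 under the other size factors, filters, tests and the replicate block. They moved with the GC and length correction (1299) and with single libraries left out (214 to 3030). Fewer libraries give fewer calls, but 3030 passed without UBE2N shRNA replicate 1. In genes above a mean log2 CPM of 5, its log2 differences from replicates 2 and 3 had SDs of 0.175 and 0.234. Between replicates 2 and 3 the SD was 0.107, so leaving replicate 1 out lowers the spread within the group. Whether this accounts for the whole rise to 3030 was not tested. Genes changed at least 2-fold numbered 62 to 170 without single libraries, 170 being without UBE2N shRNA replicate 1. With an estimated correlation 0 lists were called, against 7 to 11 under the other alternatives. With the replicate number as a block 622 genes, 100 genes changed at least 2-fold and 8 lists were called, and UBE2N had a log2 fold change of -0.46; same-numbered libraries deviated with correlations of 0.11, 0.06 and -0.05, so the numbers were not taken as pairs. Of 58 named calls besides UBE2N, 33 held without any single library, 25 were lost without at least 1, 4 were lost under another alternative and 0 changed direction. Of 21 named genes not called, 4 passed under some alternative and 12 changed direction, the cause of which was not tested. Without single libraries their log2 fold changes ranged from -0.116 to 0.263 for UBE2V1, -0.0849 to 0.128 for UBE2V2, -0.149 to 0.000376 for TRAF6, -0.0167 to 0.0657 for NFKBIA, -0.0834 to 0.0286 for HOXA9, -0.0533 to 0.0193 for MYC, -0.113 to 0.00745 for FLT3, -0.0436 to 0.0135 for CDKN1A, -0.00598 to 0.0877 for IKBKB, -0.0277 to 0.0627 for IRAK3, -0.0114 to 0.0149 for MCM7 and -0.0547 to 0.321 for CD79A. With the GC and length correction UBE2V2 stood at -0.0309, MCM7 at -0.0363 and CD79A at -0.00840. Total counts alone gave -0.00667 for IRAK3 and -0.0143 for MCM7, which stood at -0.00278 with no filter and -0.00178 with DESeq2. The direction of the camera test changed under some alternatives for 4 lists not called, whose medians lay near 0, and the cause was not tested. Without single libraries, the median log2 fold change of the list cell cycle and DNA replication ranged from -0.0708 to 0.0295, the median log2 fold change of the list DNA damage tolerance and repair from -0.0394 to 0.0436 (0.00253 with the GC and length correction), the median log2 fold change of the list mitochondrial respiration from -0.0474 to 0.00494 and the median log2 fold change of the list apoptosis regulators from -0.0183 to 0.0226. Where that of the apoptosis list turned down, its median, below 0 already, was -0.00765 with RLE size factors, -0.0231 with total counts alone, -0.0116 with no filter, -0.00690 with the replicate block and -0.0133 with the GC and length correction. Low counts limit genes near 1 CPM or below.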

Other observations

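The tests of the split of the stress list, the 2-fold calls, the calls without UBE2N shRNA replicate 1, that replicate's residual spread and cells without the hairpin were chosen only after the result was seen, as was the control hairpin test.

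Further genes, chosen after their values were seen, moved beside the lists. RGS16 and RGS2, which like RGS1 dampen G-protein signalling, rose, RGS16 from 51.7 ± 2.32 to 119 ± 13.6 CPM and RGS2 by 1.01 on the log2 scale. TSC22D3, a glucocorticoid and FOXO target, went from 36.6 to 82.9 CPM, and PPARD, a lipid-sensing receptor that induces ANGPTL4, from 50.5 to 98.0 CPM. CSF1, the ligand of CSF1R, went from 1.02 to 3.19 CPM, while IRF8, a monocyte lineage factor, fell from 489 ± 9.03 to 405 ± 5.32 CPM (edgeR adjusted p = 0.0102) and MS4A6A from 117 to 92.2 CPM.

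The integrated stress list divided into 26 amino acid and other ATF4 genes, of which 19 rose with a median of 0.57, and 16 endoplasmic reticulum chaperone and unfolded protein response genes, of which 1 rose with a median of -0.0429 (permutation p = 0.00024 for the difference). The chaperone genes as a group thus did not share the rise. Endoplasmic reticulum stress can itself raise ATF4 genes, so the split does not decide whether it was the source. An amino acid or other ATF4 response is a hypothesis. Cytosolic aminoacyl-tRNA synthetase genes, which such a response would raise, had a median of 0.0465, and 5 of 20 rose (AARS, CARS, GARS, MARS and WARS, whose 3′ UTR holds GAAGAGCA). The camera p of this list alone was 0.0792, which leaves that explanation open.

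A hairpin can lower unintended transcripts through short matches in their 3′ UTRs. Over 15509 sites of 7 bases in 9743 genes, the lowest z was -3.94, inside the limit of -4.23 from 100 permutations of the genes, while 50 of 50 trials with an added shift of -0.1 were found. This argues against seed matches of the UBE2N hairpin as a source of falls of that size, and leaves smaller ones and longer matches open.

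The upper tail of that scan held 2 sites above the permutation limit of 4.75, GAAGAGC at 5.97 and AAGAGCA at 5.86. The 434 genes with the joint 8-base sequence GAAGAGCA in the 3′ UTR were higher in UBE2N shRNA cells by 0.06 (SE 0.0090) on the log2 scale. Genes with either 7-base site in the 3′ UTR were higher by 0.0267 and those with it elsewhere in the transcript alone by 0.0119, a difference of 0.0148 (permutation p = 0.00214). The choice of the highest sites favours these values. To remove the effect of that choice, the 2 highest sites were picked in 1 part of the genes and compared in the other: 1 part gave the same pair of sites, the other ATTTATT and ATTCGCC. Over both, genes with a site in the 3′ UTR exceeded those with it elsewhere by 0.0068 (permutation p = 0.234). The difference was 0.0063 for the same pair and 0.0074 for the other pair. The p-value pools the 2 pairs, so it does not test GAAGAGC and AAGAGCA alone and decides neither way. GAAGAGC and AAGAGCA lie in the 21-base target of a widely used non-mammalian control hairpin. That target was recalled from general knowledge only after the sites were seen, and the sources do not give the control hairpin's sequence. Of the 15 sites of that target that were scanned, the others had z of -2.31 to 2.45. The 2 at its 3′ end, AGCACCA and GCACCAA, had -2.13 and 0.52. Seed matches of a hairpin would lie at that end of its target, and GAAGAGC and AAGAGCA lie further in. These values go against seed matches of that hairpin unless its processed strand begins elsewhere, which was not measured. That the control hairpin lowered genes with GAAGAGC or AAGAGCA in control cells is a hypothesis that stays open. It bears on TULP3, with 3 of the 8-base sites (4.52 to 11.6 CPM), COX7C and ARPC3 (247 to 363 CPM). Their log2 fold changes of 1.37, 0.83 and 0.55 lie far above the mean shift of 0.06, so that shift does not account for their rises. Of 11282 genes not called, 472 held the 8-base sequence. Of 398 called rises with a known 3′ UTR, 29 (7.29%) held GAAGAGCA. Of 82 called falls 3 held it, and of all genes other than the called rises 4.18% did. The site was picked for its higher genes in these data, which favours the share among rises. The medians of the 4 lists weighed below moved little without genes holding the 8-base sequence, to 0.47, 0.27, 0.39 and 0.29.

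More genes rose than fell, at 83.6% of 507 calls. With the GC and length trends removed 47.7% of 1299 calls rose, and without UBE2N shRNA replicate 1 53.1% of 3030 did. These shares moved because falls were added, from 83 to 679 and 1420, while rises also grew, from 424 to 620 and 1610. The GC and length fit also moved the median log2 fold change over genes from 0.0025 to -0.0286, which favours falls. What set the balance of rises and falls stays open. With the trends removed and single libraries left out, 37.9% of calls rose without UBE2N shRNA replicate 1 (1363 higher and 2230 lower) and 56.4% to 71.1% without the others. All 507 calls were also called without UBE2N shRNA replicate 1, so none of them needed it. Leaving it out lowers the spread within the group, so this does not test its extra spread as a cause. Without control replicates 1, 2 and 3 and UBE2N shRNA replicates 2 and 3 in turn, 214, 238, 218, 244 and 404 of the 507 were called. With the trends removed, 485 of the 493 calls with GC and length values were called, which argues against the trends as the source of the called rises themselves. Among genes changed at least 2-fold, 95.7% still rose with the trends removed, against 98.9% before, which argues against the trends as the cause there; without UBE2N shRNA replicate 1, 153 rose and 17 fell. The real grouping gave 507 calls and 88 of at least 2-fold, and the highest other split of the 6 libraries 0 and 0. However, 10 splits are too few for a share under 0.05, and each other split mixes the groups unequally. Whether loss of UBE2N or another effect of the hairpins raised these genes was not tested.

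The MAPK, integrated stress, sterol, and glycolysis and hypoxia lists rose together by camera with a preset correlation, but none of them passed with an estimated correlation (camera adjusted p of 0.0611, 0.116, 0.184 and 0.123). With the GC and length trends removed, the lowest ratio of a list's median to its value before was 0.917, which argues against the trends. The lowest of the 12 medians of these lists in single UBE2N shRNA libraries was 0.21, against 0.0552 as the highest in a control library, which argues against 1 library as the source. The real grouping gave 9 called lists and the highest other split 8, with too few splits for a share under 0.05. Each other split mixes the groups unequally and keeps part of their difference, so 8 is not a measure of chance. A change in culture density or nutrients between the groups was not tested and may raise the same lists.

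UBE2N shRNA replicate 1 stood apart from replicates 2 and 3. GC content and length accounted for 22.3% of the variance of its difference from them, which leaves a technical part open. With the trends removed the lower of its SDs from them was 0.142, against 0.0808 in the highest other pair of a group, so the trends were not the whole cause. A share of cells without the hairpin would shrink all changes alike, but over all tested members the medians of the MAPK and sterol lists were larger in it, at 0.65 and 0.63, against 0.24 to 0.39 in replicates 2 and 3, while those of the monocyte and neutrophil lists were smaller, at 0.13 and 0.05, against 0.10 to 0.24. Lists that move apart in this way argue against such cells as the whole cause. Genes called only without this library kept a ratio of 0.130 of their change, against 0.823 for UBE2N, but they were selected on replicates 2 and 3, which lowers that ratio.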
